A study of Mus musculus with 2 samples.

How the data were processed

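Chromatin accessibility was measured by ATAC-seq in lung of B6NCrl mouse embryos of mixed sex at embryonic day 16.5, per the labels, with 2 biological replicates in 1 group. Replicate 2 came from 41 embryos and no number is given for replicate 1, per the labels. Chromatin was tagmented with the Nextera transposase, and fragments of 200 to 750 bp were kept, per the labels. Reads were aligned to the mm10 assembly, per the labels. The aligner, the peak caller, the handling of the transposase offset and their versions are not given in the sources used here. The deposited files hold peaks and no reads, so the depth of each replicate is unknown and no value here rests on a read count.

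For each replicate the authors deposited a list made before a threshold on the irreproducible discovery rate (IDR), a list past the threshold and a ranked list, per the text files deposited beside them. The files shared by both replicates are a conservative list from the true replicates, an optimal list, a list of peaks found in both replicates by overlap, and the matching ranked lists, per the same text files. Each peak carries a signal value given by the authors' peak caller, whose normalization is not stated. The deposited columns of −log10 p-values and −log10 q-values come from the same caller. The ranked lists also carry a score, which in the deposited values runs from 0 to 5 and equals −log10 of the global IDR, capped, and every peak of the thresholded lists had a score at or above that of an IDR of 0.05. A region can hold several summits, each with its own signal value. Regions were therefore counted once, with the highest signal value of their summits.

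The conservative list was the main set, because it draws on both replicates. Autosomes, X and Y were used (21 chromosomes). Gene positions came from the GENCODE M21 annotation of the same assembly, with 21938 protein-coding genes. A region was a promoter region when it overlapped the 1000 bp on either side of any annotated transcript start, and distal otherwise. Distal regions were assigned to the nearest 5′ end of a coding gene within 50000 bp. A place given within a gene, such as a UTR or intron, is that of the summit, or of the middle for regions of the shift between replicates. A gene's promoter signal was the highest value among its promoter regions. In the replicates it was taken from each replicate's own list before the IDR threshold, so it can come from another region than the value of the main set. The mean and SD over the replicates are of these values.

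Replicate lists were compared by overlap of at least 50% of either region with bedtools 2.31.1, and chance was the mean of 100 placements of the regions at random on their chromosomes. Shares carry 95% Wilson intervals, which cover counting error only. The design assumed signal values of both replicates in the true-replicate ranked list. The columns for the replicates there hold −log10 p-values, without naming which replicate is which, so the correlation used log2 of those values and nothing else was taken from them. For differences between replicates, each replicate's ranked list was matched to the summits of the main set within 150 bp, and log2 ratios of signal values were centred on their median.

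The 34 gene lists cover lung epithelium (distal tip progenitor, alveolar type 1 and 2, airway, neuroendocrine), mesenchyme (fibroblast, smooth muscle and pericyte, mesothelium), endothelium (blood vessel, lymphatic), blood (myeloid, lymphoid, erythroid), other organs (Schwann cells and autonomic neurons, hepatocyte, cardiomyocyte, skeletal muscle, central neuron, intestine, pancreas, kidney, epidermis, germ cell), signalling (FGF, WNT, hedgehog, BMP and TGF-beta, Notch, retinoic acid), HOX groups 1 to 5 and 9 to 13, housekeeping, cell cycle, and olfactory and vomeronasal receptors. They were matched to the annotation by symbol. In the erythroid list 1 symbol was not matched, and its Hba and Hbb members are near-identical copies at which reads can be hard to place. Some genes stand in several lists, such as Etv5, Fgf10, Hhip, Hes1, Pdpn and Trp63.

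Open promoters of a list were compared with those of all other coding genes by Fisher's exact test, two-sided. Distal regions per gene were compared with 10000 random lists of the same size matched on decile of gene length, by a permutation test, two-sided. Both were adjusted over the 34 lists by the Benjamini-Hochberg method with a threshold of 0.05. For the shift between replicates, the list median was placed among 10000 random region sets matched on signal decile, and lists with fewer than 10 regions were left out, which left 26. For motif enrichment, promoter and distal were set by whether the summit, not the region, lay within 1000 bp of an annotated transcript start. Consensus sites of 34 motifs were sought on both strands in windows of 151 bp centred on summits (75 bp to each side). They were compared with the same windows shuffled with dinucleotide counts kept, by Fisher's exact test, two-sided. A motif was enriched with an adjusted p under 0.05 and a ratio of at least 1.5, and depleted with a ratio as far below 1. Regions are not independent replicates, so the replicates' own ratios are given as the spread. Alignment to the mitochondrial genome was sought with blastn 2.17.0 and counted from 50 bp at 80% identity.

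Genes were named by a rule fixed beforehand. It took a fixed set of 20 genes whatever their values, up to 3 members of each list that passed a test with the highest promoter signal and up to 2 without a promoter region in alphabetical order, the 5 genes with the most distal regions, the 3 regions with the highest signal value, and up to 3 regions with the largest difference for each list outside percentiles 2.5 to 97.5. Alternatives were other promoter windows (500 and 2500 bp), the 5′ end alone, the optimal and the overlap-based lists, the regions above the median signal value, each replicate left out, matching on CpG ratio, other distances (20000 and 100000 bp), counting every gene in reach, flanking windows as background and other motif windows (50 and 150 bp). The matching of random lists on the span nearest to a gene, or on gene length and an open promoter, the promoter test against 10000 random lists without matching, and the correlation of signal values were added after seeing the data. Coordinates of genes on chromosome 18 are not reported here.

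The steps were tested on simulated data with seed 1. With 98% of promoters open against 60%, 111 of 120 planted lists were recovered (92.5%) and 2 of 420 unchanged lists were called. With 3-fold more distal regions, 119 of 120 were recovered (99.2%) and 2 of 420 were called in error. A shift of 0.15 on the log2 scale over 40 regions was recovered in 173 of 200 cases (86.5%), with 10 of 200 unchanged lists outside the limits (5%). All 5 motifs planted in 5% of windows were recovered, and none of the other 29 was called. In this motif check the windows were themselves shuffled sequence. It therefore could not show calls that arise from features of real sequence beyond dinucleotide counts. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.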

Results

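Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters where DNA is accessible, in whole lung of mouse embryos (strain B6NCrl, both sexes pooled) at embryonic day 16.5. At this stage the epithelial tips are still branching and the first alveolar cells are forming. There was 1 group with 2 biological replicates, each a pool of embryos. The labels give 41 embryos for replicate 2 and no number for replicate 1. The files hold peak lists on the mm10 assembly and no read counts, so the sequencing depth of each replicate is unknown. Signal values are the authors' own value for each region. Where 1 value is given it comes from the list of regions that passed the irreproducible discovery rate (IDR) threshold across both replicates, called the main set, and a mean ± SD (n = 2) is over the replicates' own lists. The design has no second group, so it addresses where chromatin was open in this tissue, at which genes, and how far the replicates differed.

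The main set held 42316 regions with a median width of 800 bp, which covered 35.6 Mb or 1.31% of the genome. Replicate 1 alone gave 37690 regions and replicate 2 gave 24857, a ratio of 1.52. Of the replicate 2 regions, 23639 (95.1%, 95% Wilson interval 94.8 to 95.4) overlapped a replicate 1 region, against 1.59% when regions were placed at random. In the other direction 23494 of the replicate 1 regions (62.3%, interval 61.8 to 62.8) overlapped a replicate 2 region, against 1.04% at random. By the looser rule of any overlap, 14176 regions were in the list of replicate 1 alone. They had a median signal value of 5.78, below the 9.70 of its shared regions, and 21.4% of them lay at a promoter against 55.6% of the shared ones. Across the 96286 regions ranked in both replicates, log2 of the −log10 p-values correlated with r = 0.903 and Spearman's rho = 0.839. These coefficients are across regions, which are not independent replicates, so they carry no p-value, and all intervals cover counting error only.

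Open regions at promoters of annotated genes had higher signal values, by the median, than those in introns or between genes. In the main set, 16782 regions (39.7%, interval 39.2 to 40.1) overlapped the 1000 bp on either side of an annotated transcript start, 4.60 times the 8.61% found at random. The share was 48.2% ± 7.74 (SD, n = 2) in the replicates' own lists, 42.7% in replicate 1 and 53.7% in replicate 2. Placed by their summits, 37.7% of the regions were promoters, 31.8% were in introns, 27.2% were intergenic and 3.27% were in exons away from promoters. The median signal value was 10.1 at promoters, 6.24 in introns and 6.66 between genes. Of 21938 protein-coding genes, 13692 (62.4%) had an open promoter, meaning a main-set region within 1000 bp of any annotated start. The share was 61.3% from replicate 1 alone and 55.8% from replicate 2 alone.

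The 3 highest signal values of the main set belonged to narrow regions between genes. They were 55.1 at chrX, 143482935 to 143483180, with Pak3 the nearest gene at 35531 bp, 50.7 at chr2, 69355469 to 69355735, with Abcb11 at 12986 bp, and 43.1 at chr2, 3964420 to 3964690, with Frmd4a at 53156 bp. The second of these aligned to the mitochondrial genome over 129 bp at 100% identity, which limits how far its reads can be placed. Among the named genes the 2 highest promoter values belonged to cell cycle genes. Mcm3, a subunit of the replicative helicase, had 20.3 (19.5 ± 1.68, SD, n = 2), and Ccna2, which encodes cyclin A2, had 19.3 (19.1 ± 0.177, SD, n = 2).

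Promoters of distal tip progenitor genes were open in 18 of 19 cases (94.7%, interval 75.4 to 99.1). The list was drawn up for the tips of the branching epithelium and also holds factors of the wider lung epithelium such as Nkx2-1. Fisher's exact test against all other coding genes, two-sided, gave adjusted p = 0.00601. The call ended against random lists matched on promoter CpG ratio (82.6% open; adjusted p = 0.297 by a permutation test), and by the exact test with a window of 500 bp (adjusted p = 0.0803) and above the median signal value (adjusted p = 1). Etv5, an ETS factor induced by FGF signalling, had a signal value of 12.8 (14.8 ± 0.755, SD, n = 2) at chr16, 22439169 to 22440553, with the summit just upstream of the gene. Spry2, a feedback inhibitor of FGF receptors, had 12 (12 ± 0.573, SD, n = 2), and Foxp1, a forkhead repressor, had 11.1 (10.4 ± 1.21, SD, n = 2). The Foxp1 region lay in an intron at another annotated start, 494405 bp from its 5′ end. Nkx2-1, the homeodomain factor that specifies lung epithelium, had 4.76 (4.47 ± 0.816, SD, n = 2) at chr12, 56534828 to 56536318, with the summit in an intron. Sox9, a factor of the distal tips, had 7.88 (7.63 ± 0.841, SD, n = 2) at chr11, 112781603 to 112782804, with the summit upstream of the gene. The member without a promoter region was Shh, the ligand that the epithelium sends to the mesenchyme, which had 3 distal regions in the main set and 5 and 3 in the lists of replicates 1 and 2. For all gene lists the p-values were adjusted by the Benjamini-Hochberg method over 34 lists. The lists, windows and tests were chosen before the data were examined.

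Marker lists of differentiated epithelium did not pass the promoter test. Of the alveolar type 2 markers, which belong to the surfactant-making cell, 13 of 20 were open (65.0%, interval 43.3 to 81.9; adjusted p = 1 by Fisher's exact test). Lpcat1, an enzyme of surfactant lipid synthesis, had 14.0 (13.1 ± 1.22, SD, n = 2) and Abca3, the lipid transporter of lamellar bodies, had 11.4 (11 ± 0.0973, SD, n = 2). Sftpb, encoding surfactant protein B, had 7.48 (7.15 ± 1.47, SD, n = 2) at chr6, 72303584 to 72304782, with the summit upstream of the gene. Sftpc, encoding surfactant protein C, had no promoter region in the main set, and its highest values were 2.15 and 2.78 in the replicates' lists before the IDR threshold. Chil1 and Hc were also without one in the main set, and Chil1 had 4.15 and 3.59 in the replicates before the threshold. Of the alveolar type 1 markers, which belong to the flat gas-exchange cell, 15 of 18 were open (83.3%, interval 60.8 to 94.2; adjusted p = 0.120 by Fisher's exact test). They were led by Rtkn2 at 13.8, Akap5 at 11.8 and Emp2 at 11.6. Ager, a receptor abundant in these cells, had 4.83 (5.60 ± 1.28, SD, n = 2) at chr17, 34597544 to 34598424, with the summit upstream of the gene. Hopx, a homeodomain-only cofactor, had its strongest promoter region of the main set at chr5, 77094653 to 77095465, with 8.58. This region had 7.76 in replicate 1 and 9.35 in replicate 2. It lies in an exon of the non-coding gene Hopxos, 19824 bp from the 5′ end of Hopx, at another annotated start. A second main-set region, at chr5, 77114786 to 77116116 with 7.31, spans the 5′ end of Hopx. There replicate 1 had 7.92, and replicate 2 had no region past the IDR threshold. Aqp5, the water channel, and Cyp2b10 had none in the main set, and Aqp5 had 4.83 in replicate 1 before the threshold. In the optimal list the type 1 list had adjusted p = 0.0424 and in the overlap-based list 0.0369, by the same exact test.

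Among the airway markers 12 of 22 promoters were open (54.5%, interval 34.7 to 73.1; adjusted p = 0.598 by Fisher's exact test), and the strongest belonged to genes of ciliated cells. Rfx3 and Rfx2, factors of cilium genes, had 17.0 (16.5 ± 1.43, SD, n = 2) and 16.0 (15.2 ± 1.59, SD, n = 2). Ccno, needed to make multiple cilia, had 16.5 (15.7 ± 0.724, SD, n = 2). Foxj1, the main regulator of motile cilia, had 9.98 (9.45 ± 0.952, SD, n = 2) at chr11, 116335127 to 116336028, with the summit upstream of the gene. Sox2, the factor of proximal airways, had 8.16 (7.79 ± 0.279, SD, n = 2) at chr3, 34649245 to 34650201, in an intron of the overlapping transcript Sox2ot. The secretory-cell genes Scgb1a1, Cyp2f2 and Bpifa1 had no promoter region in the main set, and neither did Mcidas and Dnah5 of ciliated cells, while Aldh1a7 (8.01), Muc5b (6.66) and Cbr2 (3.04) of secretory cells had one. Mcidas, Dnah5, Aldh1a7, Muc5b and Cbr2 were chosen after their values were seen, and the 2 kinds of airway cell were not compared by a test. Of the neuroendocrine markers 7 of 12 were open (adjusted p = 0.847 by Fisher's exact test).

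Fibroblast and mesenchyme promoters were open in 24 of 25 cases (96.0%, interval 80.5 to 99.3; adjusted p = 0.000644 by Fisher's exact test). Col1a2, a chain of type I collagen, had 14.0 (13.4 ± 0.890, SD, n = 2) at chr6, 4504745 to 4506027, in its UTR. Fn1, encoding fibronectin, had 12.5 (12.1 ± 0.991, SD, n = 2). Macf1, a cytoskeletal linker, had 11 at another annotated start, 272363 bp from its 5′ end. The exception was Lum, a proteoglycan gene, which had 3.14 in replicate 1 before the IDR threshold. Foxf1, a mesenchymal forkhead factor, had 7.08 (7.29 ± 0.174, SD, n = 2) at chr8, 121083000 to 121084667, in an intron of Gm20388. Tbx4, a T-box factor of lung mesenchyme, had 5.97 (6.28 ± 0.0708, SD, n = 2) at chr11, 85885759 to 85886638, with the summit upstream of the gene. Fgf10, the growth factor that drives branching, had 5.64 (5.09 ± 1.29, SD, n = 2) at chr13, 118714207 to 118716082, an intronic start 44765 bp from its 5′ end. Without replicate 1 this list had 19 of 25 open and adjusted p = 0.0638 by the same exact test, and with the gene's 5′ end alone adjusted p = 0.152. With the regions above the median signal value the list lay below other genes (adjusted p = 0.644 by that exact test).

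Smooth muscle and pericyte promoters were open in 15 of 17 cases (88.2%; adjusted p = 0.0640 by Fisher's exact test). The same exact test gave adjusted p = 0.0392 with a promoter window of 500 bp, 0.0177 with 2500 bp and 0.0247 with the 5′ end alone, so this call depended on the setting. Acta2, encoding smooth muscle actin, had 9.94 (8.80 ± 0.299, SD, n = 2) at chr19, 34255197 to 34255741, in its UTR. Blood vessel endothelium had 19 of 24 open (79.2%, interval 59.5 to 90.8; adjusted p = 0.126 by Fisher's exact test). Its strongest members were Ets1, an ETS factor, with 14.1 (14.5 ± 0.0294, SD, n = 2), Tie1, a receptor kinase, with 13.6 (12.3 ± 1.02, SD, n = 2), and Kdr, the main VEGF receptor, with 9.22 (9.03 ± 0.108, SD, n = 2). The Ets1 region lay at another annotated start, 59803 bp from its 5′ end. Car4, Emcn and Pecam1 had no promoter region in the main set, and Emcn had 2.51 in replicate 1 before the IDR threshold. Pecam1, encoding an adhesion protein of endothelium, had 3.14 in replicate 1 and 5.65 in replicate 2 there. The endothelial list passed in the overlap-based list (adjusted p = 0.0079 by the same exact test). Lymphatic endothelium had 5 of 8 open (adjusted p = 1 by Fisher's exact test) and mesothelium 7 of 12 (adjusted p = 0.847 by Fisher's exact test), and without replicate 1 mesothelium had 2 of 12 and adjusted p = 0.0152. Wt1, the mesothelial zinc-finger factor, had 5.34 (5.20 ± 0.707, SD, n = 2) at chr2, 105126211 to 105126934, in its UTR.

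All members of several signalling and general lists had an open promoter. These were the BMP and TGF-beta pathway (22 of 22, adjusted p = 0.000403 by Fisher's exact test), WNT (20 of 20), housekeeping (20 of 20) and cell cycle (20 of 20, each adjusted p = 0.000417), Notch (15 of 15, adjusted p = 0.00256) and FGF (14 of 14, adjusted p = 0.00354). The leading promoters were Tgfbr1, a TGF-beta receptor, with 18 (17.2 ± 1.07, SD, n = 2), Hey2, a Notch target, with 16.6 (15.8 ± 0.475, SD, n = 2), Maml1, a Notch coactivator, with 16.2, and Fzd4, a WNT receptor, with 12.4 (11.8 ± 0.530, SD, n = 2). In the BMP and WNT lists Smad2 had 13.9, Acvr1 13.1, Lrp6 11.6 and Tcf7l1 11.6. In the FGF list Etv5 and Spry2 were followed by Dusp6, a phosphatase of the ERK pathway, with 11.6. Rplp0 had 17.7, Sdha 17.4, Tfrc 17.1 and Pcna 18 in the general lists. The hedgehog pathway had 11 of 12 open (adjusted p = 0.0620 by Fisher's exact test, 0.0350 with the 5′ end alone and 0.0416 in the overlap-based list) and the retinoic acid pathway 11 of 15 (adjusted p = 0.532 by Fisher's exact test). Replicate 2 alone had 13 of 20 WNT promoters open (adjusted p = 0.589 by Fisher's exact test), so that call ended without replicate 1. Above the median signal value the WNT (0.367), BMP (0.384), FGF (0.297) and Notch (0.848) lists had an adjusted p over the threshold by the exact test, and the Notch list lay below other genes. Against lists matched on promoter CpG ratio all but the Notch call ended.

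Promoters of 10 lists of blood and other organs were open less often than those of other genes. The counts were 1 of 17 for myeloid cells (5.88%, interval 1.05 to 27.0; adjusted p = 2.9e-05 by Fisher's exact test), 4 of 16 for lymphoid cells (adjusted p = 0.00601) and 2 of 15 for erythroid cells (adjusted p = 0.000501). The same exact test gave adjusted p = 0.000114 for hepatocytes (2 of 18 open) and 0.000513 for both intestine and epidermis (1 of 12 each). It gave 0.00354 for pancreas and kidney (2 of 12 each), 0.0216 for skeletal muscle (4 of 14) and 0.0313 for central neurons (7 of 20). Against lists matched on promoter CpG ratio, 6 of these 10 calls ended (myeloid, lymphoid, erythroid, hepatocyte, skeletal muscle and epidermis, with adjusted p from 0.216 to 0.618 by a permutation test). In the overlap-based list central neurons lay above other genes (adjusted p = 0.887 by the exact test), and pancreas (0.0786), kidney (0.260) and skeletal muscle (0.0673) did not pass. Ptprc, the pan-leukocyte gene, Gata1, the erythroid factor, and Alb, encoding albumin, had no promoter region in the main set or in either replicate's list before the IDR threshold. Myod1, the muscle factor, and Neurod1, a neuronal factor, had one only in the list of replicate 1 before the IDR threshold, at 2.13 and 4.02. Genes without a promoter region in the main set included Adgre1 and C1qa of macrophages, Cd19 and Cd3d of lymphocytes, Alas2 and Epb42 of red cells, Afp and Ahsg of liver, Acta1 and Chrna1 of muscle, and Dlx2 and Eomes of neurons. Others were Alpi and Cdh17 of intestine, Amy2a5 and Cpa1 of pancreas, Aqp2 and Hnf1b of kidney, and Dsg1a and Flg of skin. Of these, Eomes (6.53 and 4.39) and Hnf1b (3.77 and 3.76) had a region in both replicates' lists before the IDR threshold, and Cdh17 (4.02), Cpa1 (3.31) and Dlx2 (2.46) in that of replicate 1. Over the 11 lower lists other than the receptor genes, 136 of 164 members had no region in the main set, and 99 of these had none in either list before the threshold. The lists that did not pass were cardiomyocytes (7 of 16, adjusted p = 0.164), germ cells (4 of 12, adjusted p = 0.101) and Schwann cells and autonomic neurons (5 of 13, adjusted p = 0.120), by the same exact test. Without replicate 1 cardiomyocytes had 4 of 16 and adjusted p = 0.0347, and with a window of 500 bp germ cells had adjusted p = 0.0243, by that exact test. Without replicate 2 the skeletal muscle list had adjusted p = 0.0936 by that exact test.

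Some members of these other-organ lists did have strong promoter regions. Pax5, the B-cell factor, had 16.2 (16.1 ± 1.12, SD, n = 2) at chr4, 44703885 to 44704927, where the summit lies in an exon of the non-coding gene 5730488B01Rik, 5924 bp from the 5′ end of Pax5. Mafa, a factor of insulin-producing cells, had 16.2 (15.6 ± 1.1, SD, n = 2) at chr15, 75747739 to 75748851, with the summit upstream of the gene. Syt1, a synaptic vesicle protein, had 14.1 (12.2 ± 2.96, SD, n = 2), Dlx1 12.4 and Snap25 11.8. Apoa1, a liver apolipoprotein, had 11.6 at chr9, 46229719 to 46230592, in a coding exon 1537 bp from its 5′ end, and before the IDR threshold only the list of replicate 1 held it (12.8). Klf1, an erythroid factor, had 9.37 (8.78 ± 1.82, SD, n = 2), also in a coding exon, at chr8, 84902497 to 84903680. The others named by the same rule were Krt10 at 11, Mylpf at 10.9, Six2 at 8.98, Cd79b at 7.85, Tcf7 at 7.38, Lgr5 at 7.30, Cav3 at 7.06, Epor at 6.47, Tnni2 at 6.31, Cela1 at 5.44, Nr1h4 at 5.12, Lhx1 at 4.63 and Spi1 at 4.27. The Krt10 and Cela1 summits lay in coding exons, 3335 and 3300 bp downstream of the 5′ end. That of Lhx1 lay in an intron, 2749 bp downstream.

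HOX genes of the anterior paralogue groups 1 to 5, which are active in lung, had 9 of 15 promoters open (60%, interval 35.7 to 80.2; adjusted p = 1 by Fisher's exact test). Without replicate 1 they had 3 of 15 and adjusted p = 0.0152 on the lower side, and in the overlap-based list 0.0169 on the higher side, by the same exact test. The posterior groups 9 to 13 had 2 of 16 open (12.5%, interval 3.50 to 36.0; adjusted p = 0.000403 by Fisher's exact test), which were Hoxd10 at 7.53 (6.68 ± 1.85, SD, n = 2) and Hoxc13 at 6.74 (5.85 ± 0.812, SD, n = 2). Hoxa10 and Hoxa11 were among those without a region in the main set, and Hoxa10 had one in both replicates' lists before the IDR threshold (5.92 and 3.59). Before that threshold 10 of the 16 genes had a region in replicate 1 and 8 in replicate 2, and in the overlap-based list the call ended (adjusted p = 0.669 by the exact test). Olfactory and vomeronasal receptor genes had 5 of 1421 open (0.352%, interval 0.15 to 0.821), with a p too small for the software to represent. They were led by Vmn1r4 at 15.2, Olfr71 at 8.42 and Olfr56 at 5.98, while Olfr1 and Olfr10 had no region. The difference between anterior and posterior HOX lists was not itself tested, and neighbouring HOX or receptor genes can share a region.

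In all, 20 of the 34 lists differed from other genes, 8 with more open promoters and 12 with fewer. The share of open promoters rose with promoter CpG content, from 6.75% in the lowest decile of the CpG ratio to 97.7% in the highest. A permutation test against random lists without matching, chosen after the data were seen, called the same 20 lists. Against random lists matched on the CpG ratio, 8 of these calls were kept by the same permutation test and 2 lists were gained, smooth muscle (88.2% against 56.9%, adjusted p = 0.0187) and germ cells (33.3% against 77.2%, adjusted p = 0.00136). By permutation, the fibroblast and Notch lists stayed higher (adjusted p = 0.00136 and 0.0374), and central neuron (0.00136), intestine (0.0189), pancreas (0.0187), kidney (0.0187), posterior HOX (0.00136) and olfactory receptors (0.00136) stayed lower. The distal tip (adjusted p = 0.297), myeloid (0.216), lymphoid (0.358), erythroid (0.618), hepatocyte (0.221), skeletal muscle (0.358), epidermis (0.358), housekeeping (0.0507), cell cycle (0.526), FGF (0.144), WNT (0.268) and BMP (0.202) calls were lost in the same permutation test. The cell cycle, FGF, WNT and BMP lists were wholly open and the central 95% of their matched random lists reached 100%, so those 4 calls could not have been kept. Other settings ended the distal tip, fibroblast, skeletal muscle, central neuron, pancreas, kidney, FGF, WNT, BMP, Notch or posterior HOX call, each in 1 to 4 of 8 settings.

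**Figure D1:**
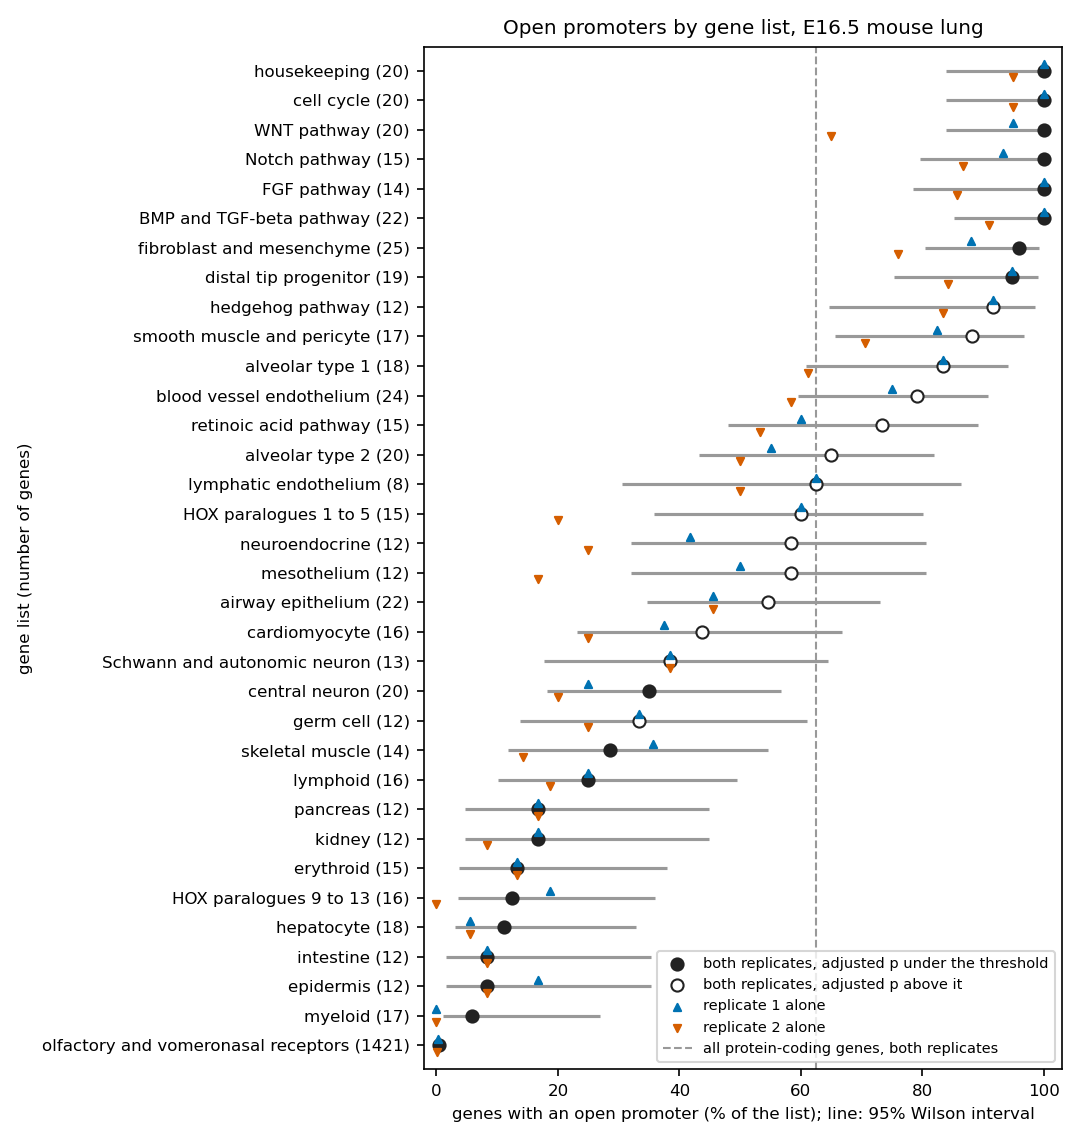
Percent of each gene list's promoters that held an open region in the main set (circles, with 95% Wilson intervals, filled where the adjusted p was under the threshold) and in each replicate's own list (triangles), against the share of all coding genes (dashed line at 62.4%). Distal tip (94.7%), mesenchymal (96.0%) and signalling lists lie above the line, and blood and other-organ lists such as myeloid (5.88%) lie below it.

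Away from promoters, 10 of the 34 lists had more open regions per gene than random lists. They were the distal tip, alveolar type 1 and 2, airway, fibroblast, blood vessel endothelium, FGF, WNT, BMP and TGF-beta, and Notch lists. Of the 25534 distal regions (60.3%), 13423 lay within 50000 bp of a coding gene's 5′ end and were assigned to the nearest one, a mean of 0.612 per gene. Notch pathway genes had 3.13 distal regions per gene, 4.94 times the 0.635 of random lists matched on gene length (4.57 ± 0.203 times, SD, n = 2). FGF pathway genes had 2.71 (3.96 times, and 5.02 ± 1.05, SD, n = 2). Distal tip progenitor genes had 2.00 (3.48 times, and 4.19 ± 0.114, SD, n = 2). Blood vessel endothelium had 2.38 (3.44 times, and 3.98 ± 0.779, SD, n = 2). For each of these 4 lists a permutation test, two-sided, gave adjusted p = 0.00113, from the smallest p that the 10000 random lists can give (0.0002).

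The same permutation test called 6 further lists higher. Alveolar type 1 genes had 2.11 distal regions per gene (3.20 times random lists; adjusted permutation p = 0.0017) and alveolar type 2 genes 1.45 (2.46 times; adjusted p = 0.0155). Airway genes had 1.41 (2.55 times; adjusted permutation p = 0.0155), fibroblast genes 1.76 (2.36 times; adjusted p = 0.00378), BMP and TGF-beta genes 2.32 (2.86 times; adjusted p = 0.00113) and WNT genes 2.15 (2.94 times; adjusted p = 0.0017). All 10 lists were above random lists in each replicate alone as well. Some of them share genes, such as Hes1 in the airway and Notch lists, so these calls are not independent. Olfactory receptor genes were lower, with 0.0267 against 0.404 (adjusted permutation p = 0.00113). Smooth muscle (2.17 times; adjusted permutation p = 0.0513), retinoic acid (2.05 times; 0.0970), hedgehog (1.94 times; 0.146) and lymphatic genes (2.27 times; 0.146) did not pass the test. In each replicate alone, retinoic acid (adjusted permutation p = 0.00994 and 0.0181) and hedgehog genes (0.0194 and 0.0252) did pass, as did smooth muscle genes in replicate 1 (0.00302). Erythroid genes and posterior HOX genes had no distal region (adjusted p = 0.0513 and 0.0970 by the permutation test). Neuroendocrine genes had 1.00 distal region per gene and adjusted permutation p = 0.228, kidney genes 1.00 and 0.489, housekeeping genes 0.9 and 0.215, and cell cycle genes 0.85 and 0.272. The remaining 13 lists, which cover the other blood, organ and neural types, mesothelium and anterior HOX genes, had adjusted p of 0.489 or more. When random lists were matched on the span in which a gene is the nearest one, the fibroblast ratio was 1.71 (adjusted p = 0.0782 by the permutation test), and when every gene within reach was counted the airway list had adjusted p = 0.0642. With the regions above the median signal value alone 5 calls were left, and alveolar type 2, airway, fibroblast, WNT, BMP and Notch genes had adjusted p from 0.051 to 0.281 by that test.

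Named loci differed widely in their distal regions. Hopx had 7, from 11572 to 40121 bp from its 5′ end, with signal values of 4.88 to 8.94 and the strongest at chr5, 77154763 to 77155447, between genes. Scgb1a1, which encodes the secretoglobin of club cells and had no promoter region in the main set, had 6 distal regions with values of 4.55 to 11.9. The strongest lay between genes at chr19, 9081754 to 9083112, 5525 bp from the 5′ end, and 3 of the 6 lay in introns of Ahnak. Ets1 had 7, Emp2 5 and Lpcat1 4, while Sftpb, Nkx2-1, Etv5 and Shh had 3 each. In the Notch list, Notch1, Hes1 and Rbpj had 8 each and Notch2 had 7. These 4 genes were chosen after their values were seen. Hes1 is also in the airway list. Its 8 regions and the 6 of Scgb1a1 are among the 31 distal regions of that list. The airway list was not tested without these genes, so its call may rest on them. In the list of replicate 2 alone Ets1, Notch1, Notch2, Hes1, Rbpj, Emp2 and Scgb1a1 had 3 each, Hopx 5, Etv5 2 and Lpcat1 and Nkx2-1 1 each. In that of replicate 1 alone Shh and Rbpj had 5 each, Lpcat1 2 and Nkx2-1 1. The genes with the most distal regions in the main set were Ncor2, a nuclear corepressor, with 12, and Trim8, Irf2bpl and Tgm2 with 11 each. The order differed in the replicates' own lists, where Ncor2 had 8 and 3, Trim8 10 and 5, Irf2bpl 9 and 7, and Tgm2 9 and 3. Kdm6b, a histone demethylase whose own promoter had no region in the main set, had 9, tied with 5 other genes, and 10 and 6 in the replicates. Assignment to the nearest 5′ end is by position alone, and genes with a far annotated 5′ end, such as Fgfr2, can lose regions to their neighbours.

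**Figure D2:**
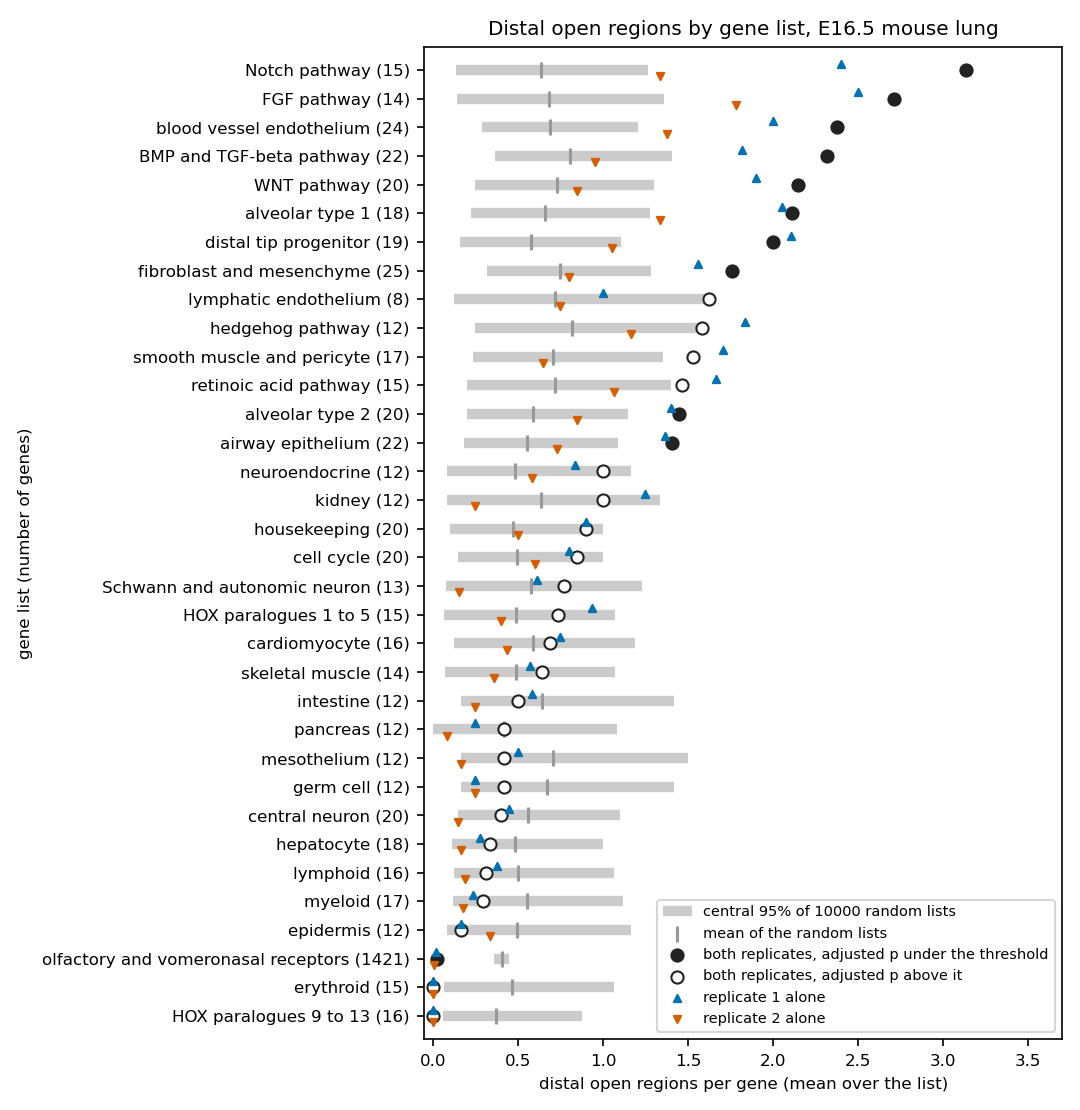
Mean number of distal open regions per gene for each gene list in the main set (circles), with the central 95% of 10000 random lists matched on gene length for the main set (grey bars), and the same mean in each replicate's own list (triangles). Notch (3.13 per gene), FGF (2.71) and endothelial genes (2.38) lie above the range of random lists, and olfactory receptor genes (0.0267) lie below it.

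**Figure D3:**
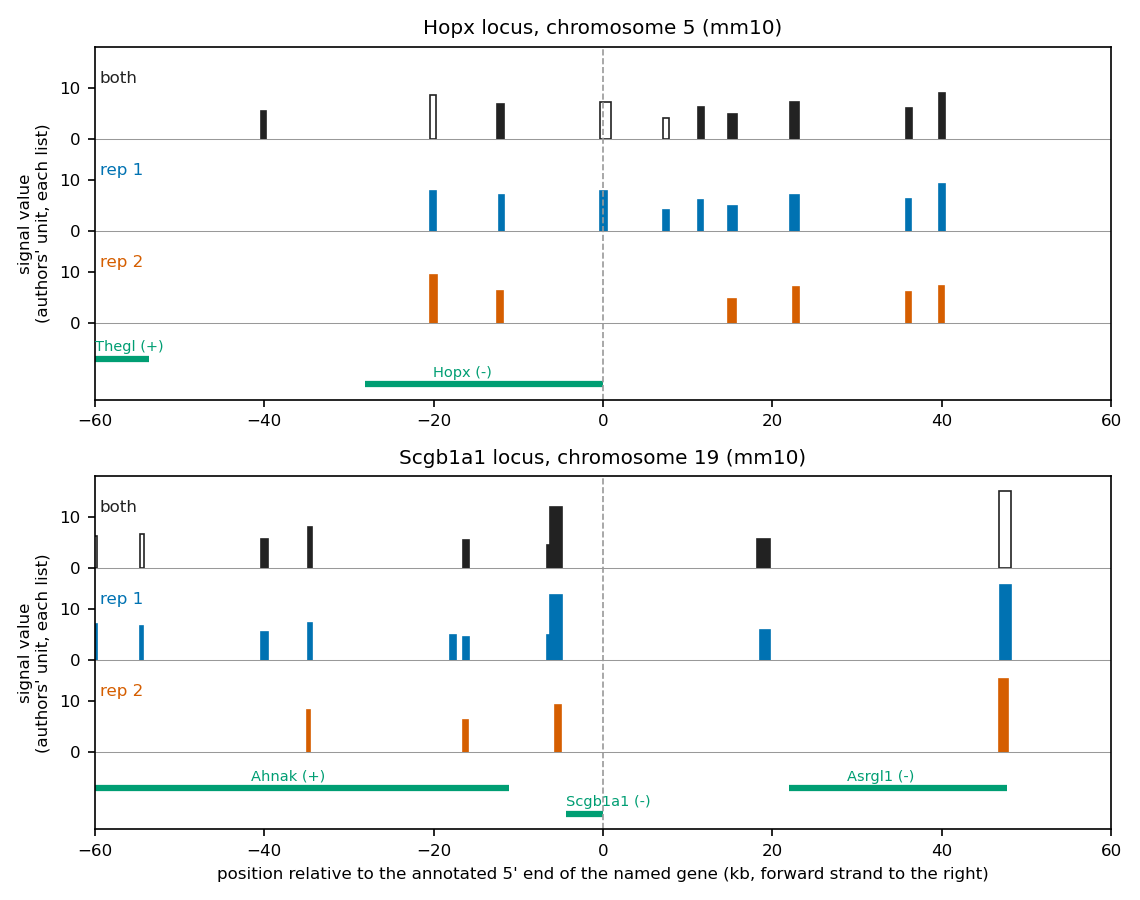
Open regions within 60 kb of the 5′ ends of Hopx and Scgb1a1 in the main set and in each replicate's own list, by position relative to the 5′ end along the horizontal axis and signal value along the vertical axis, with annotated genes drawn to scale. Filled bars in the main set are distal regions assigned to the named gene, 7 at Hopx and 6 at Scgb1a1, and the dashed line is the annotated 5′ end.

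Summits over 1000 bp from any annotated transcript start, called distal summits here, carried sites of TEAD, FOX and CTCF far more often than shuffled sequence. TEAD sites, bound by the effectors of the Hippo pathway, lay in 8.07% of 26347 distal summit windows against 1.99% of windows shuffled with dinucleotide counts kept, a ratio of 4.05 (3.76 ± 0.529, SD, n = 2). FOX sites, bound by forkhead factors, lay in 6.98% against 1.60% (ratio 4.37, and 4.49 ± 0.788, SD, n = 2). CTCF sites, which mark insulators, lay in 2.77% against 0.129% (ratio 21.4, 15.5 ± 8.05, SD, n = 2, and 9.85 without replicate 1). ETS sites lay in 4.68% (ratio 2.63, and 2.74 ± 0.224, SD, n = 2). Fisher's exact test, two-sided and adjusted over 34 motifs by the Benjamini-Hochberg method, gave 1.9e-236 for TEAD, 1.3e-217 for FOX, 5.7e-172 for CTCF and 8.2e-81 for ETS. The E-box CAGCTG was in 23.3% of distal windows (ratio 1.75). The other enriched distal motifs were SP/KLF (ratio 8.82), RFX (8.53), CREB (5.74), NFI (5.33), MEF2 (4.83), STAT (4.02), C/EBP (2.26), RUNX (1.79), GATA (1.55), AP-1 (1.52), the E-box CATATG (1.51) and NRF1 (21, with 1 background window). RFX had a ratio of 3.15 without replicate 2, SP/KLF had 5.63 without replicate 1, and for NRF1 either replicate alone had 0 background windows, so no ratio could be given (adjusted p = 0.000127 and 2.9e-05 by the exact test). Ratios near 1.5 changed side with the setting. CATATG had 1.31 to 1.42 in the optimal and overlap-based lists, above the median signal value and with windows of 50 and 150 bp, AP-1 had 1.47 in the optimal list, and RUNX had 1.47 above the median signal value. With 150 bp AP-1 had 1.32, GATA 1.30 and C/EBP 1.39. Without replicate 1 SRF (1.60), TCF/LEF (1.75) and NFY (1.66) passed as enriched and YY1 as depleted (0.636), and without replicate 2 E2F passed as depleted (0.638). NFY passed as well above the median signal value (1.73), with windows of 50 bp (1.70) and against windows 500 bp to either side (1.69). SRF (1.57) and the homeobox site TAATTA (1.73) also passed above the median signal value. TBX sites were depleted (ratio 0.561), which ended against windows 500 bp to either side (0.877; adjusted p = 0.236 by the exact test) and with 50 bp (0.689) and 150 bp (0.738). The NKX2-1 family consensus lay in 5.83% of distal windows against 6.43% of shuffled ones (ratio 0.906; adjusted p = 0.00581 by the exact test). Against windows 500 bp to either side, with 4.01%, the direction turned (ratio 1.45; adjusted p = 8.9e-29 by the exact test).

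At 15967 promoter summits the leading sites were those of general promoter factors. SP/KLF sites lay in 16.3% of windows (ratio 7.54, and 7.16 ± 0.0742, SD, n = 2), NFY in 11.9% (ratio 10.9, and 11.4 ± 0.262, SD, n = 2) and ETS in 8.42% (ratio 5.85, and 6.94 ± 1.06, SD, n = 2). CREB lay in 2.43% (ratio 38.8, and 36.1 ± 0.936, SD, n = 2) and NRF1 in 1.12% (ratio 35.8, 20 ± 8.54, SD, n = 2, and 13.9 without replicate 1). The shuffled background held 10 windows with a CREB site, 5 with an NRF1 site and 8 with an RFX site. With so few, the ratios of these 3 motifs are imprecise whatever their SD. Fisher's exact test gave adjusted p = 1.9e-199 for ETS and values too small to represent for SP/KLF and NFY. RFX (ratio 13.4), POU (7.22), CTCF (6.85), MEF2 (5.64), YY1 (5.14), STAT (3.93), FOX (3.41), SRF (2.39), TEAD (2.11), C/EBP (1.65) and AP-1 (1.56) were also enriched. Without replicate 1 the ratio was 9.48 for YY1 and 3.29 for MEF2 and the C/EBP call ended (1.26), and without replicate 2 it was 2.37 for STAT and RUNX passed as well (1.66). With 150 bp SRF (1.27), AP-1 (1.39) and C/EBP (1.1) did not pass, nor did AP-1 above the median signal value (1.36). HNF4 (0.444), TBX (0.471) and E2F (0.580) were depleted in the main set, and none of the 3 with either replicate left out, where the ratios were 0.692 and 0.867, 0.625 and 0.714, and 0.677 and 0.773. A consensus stands for a family of factors and does not show which one is bound. With windows 500 bp to either side as background, the enriched distal MEF2 (ratio 0.623), distal CATATG (0.799), promoter FOX (0.672) and promoter MEF2 (0.320) were below their background, while E2F was above it (1.64 distal, 2.32 at promoters). The same background ended the enrichment of distal GATA (ratio 1.01) and RUNX (1.03) and of promoter TEAD (1.08), POU (1.44), SRF (1.14) and AP-1 (1.14). Besides E2F, it gained distal GLI (2.25), NFY (1.69), GRHL (1.62) and HNF1 and promoter NFI (10) and CAGCTG (1.55) as enriched. At distal summits FOX and TEAD stayed enriched, with ratios of 1.61 and 2.98. Other calls kept their side with a changed ratio. It fell for distal NRF1 (10.5), SP/KLF (3.52), RFX (2.56) and STAT (1.62) and for promoter NRF1 (16.3), CREB (15.2), RFX (6.29), ETS (3.89), YY1 (2.73) and STAT (1.58). It rose for distal NFI (8), C/EBP (3.79) and CAGCTG (3.04) and for promoter C/EBP (3.09).

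**Figure D4:**
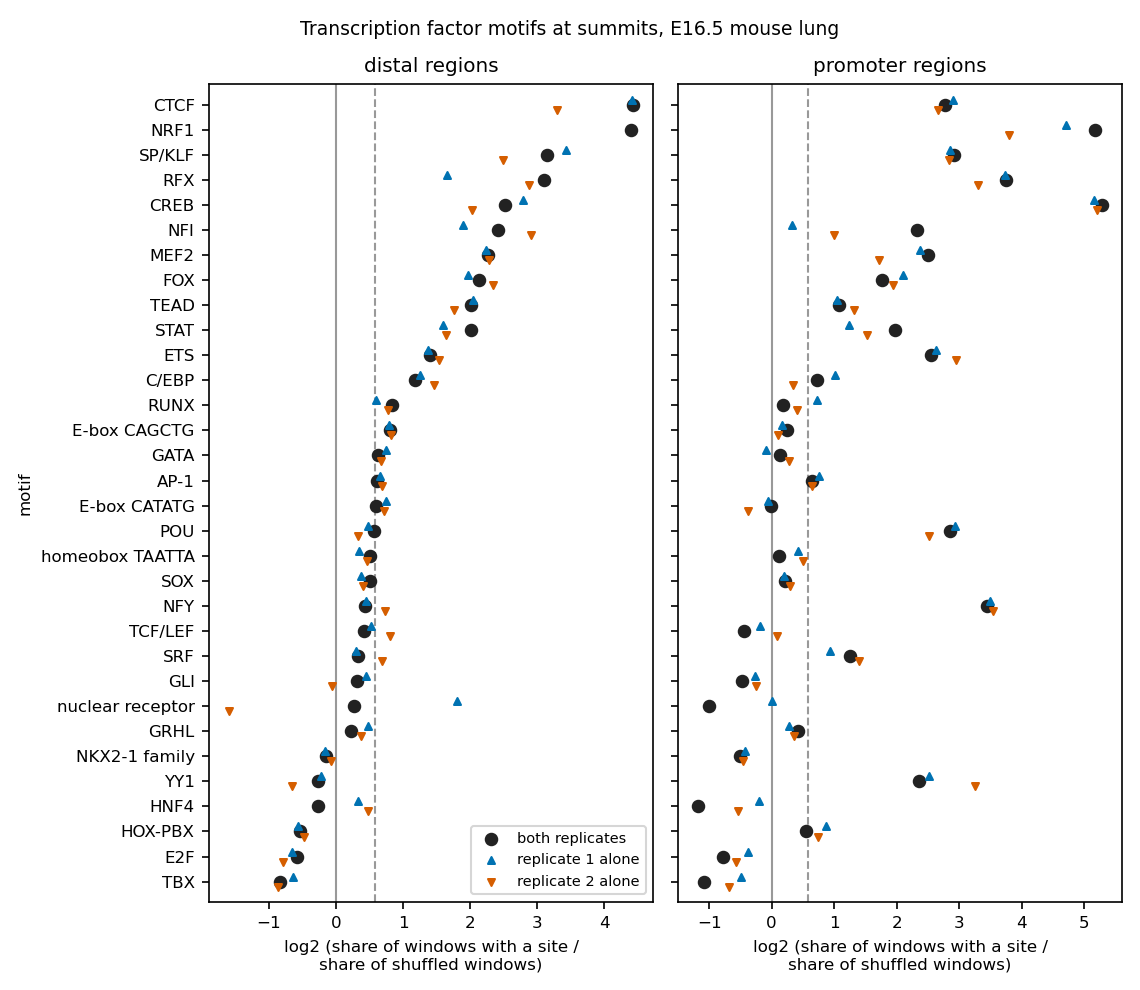
Ratio (log2 axis) of the share of summit windows with a motif to the share of shuffled windows, for distal (left) and promoter (right) regions by summit position, on separate scales, with the main set and each replicate's own list as separate symbols. CTCF at distal regions (21.4) and CREB at promoters (38.8) have the highest ratios with more than 1 background window, and the dashed line is the ratio of 1.5 needed to call enrichment.

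Signal values at the same regions were close in the replicates, and 2 gene lists fell outside the range of random sets. At the 41121 regions matched in both (97.2%), the median signal value was 7.25 in replicate 1 and 6.67 in replicate 2, a median log2 ratio of 0.11 with an SD of 0.25 across regions. After centring on all regions, distal tip genes had a median log2 ratio of −0.10 over 59 regions, at percentile 0.84 of random region sets matched on signal. Blood vessel endothelium had −0.11 over 81 regions, at percentile 0.33. Both were lower in replicate 1 only relative to all regions, and before centring both medians were close to 0. The largest differences were at a distal region of Id2 at chr12, 25119222 to 25119757, between genes, with 6.34 in replicate 1 and 8.78 in replicate 2, and at the promoter of the endothelial receptor Robo4 at chr9, 37400587 to 37401056, with 5.97 and 8.40. Others were a second Id2 region at chr12, 25092310 to 25093198 (2.57 and 3.41), the Foxa2 promoter at chr2, 148045319 to 148046743, in a Foxa2 intron (6.10 and 7.74), the Cdh5 promoter at chr8, 104101420 to 104101770, in an intron of Gm29682 (3.91 and 5.32), and a distal Flt1 region at chr5, 147751613 to 147752194, between genes (5.84 and 7.74). The other 24 lists tested lay within the central 95% of random sets, among them mesenchyme (49.3), smooth muscle (48.4), airway (32.2), alveolar type 1 (51.6), alveolar type 2 (20.5), cardiomyocytes (26.6) and the cell cycle (80.1). Myeloid, lymphoid, erythroid and hepatocyte genes had fewer than 10 such regions each and were not tested. These percentiles describe 2 libraries and are not p-values, and with distal regions alone no list fell outside (2.82 for endothelium, 12.2 for the distal tip).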

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

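In this part, only the comparison with random lists without matching and the split by lists that were wholly open were chosen after the results were seen.

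In the ranked list of the true replicates, 237 summits passed the IDR threshold and yet were absent from the conservative list, a signal outside the regions used for the comparisons. Of these, 79 lay on unplaced scaffolds and 158 on chromosomes, in 65 regions. The strongest had a signal value of 46.9 at chr9, 24541943 to 24542230, 38952 bp from Dpy19l1, and 43.3 at chr6, 103648978 to 103649356, 138612 bp from Chl1. Several lay in groups near the genes Gm21738 and Sfi1. A region at chr1, 24611586 to 24616168, with 16 summits and a −log10 p of 7899, was the only 1 of the 65 that aligned to the mitochondrial genome. The main set also holds regions that align there, and no explanation for the absences was tested further.

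The list of replicate 1 held 37690 regions against 24857 in replicate 2. Of the regions in replicate 1 alone, 89.9% overlapped a region of replicate 2 from before the IDR threshold, so most of these regions were present in replicate 2 and fell under its threshold. The lists before the threshold already differed, by a ratio of 1.33 against 1.52 after it. At the same signal value the −log10 p of replicate 1 was a median of 1.63 times that of replicate 2 over 5 bins, consistent with deeper sequencing of replicate 1. A different cell composition of the 2 tissue pools stays open, since 2 lists (distal tip and endothelium) fell outside the range of random region sets, 3 did without matching on signal, and 0 did with distal regions alone. Chance alone puts about 5% of lists outside in simulated data, so these counts decide nothing, and no biological explanation was tested.

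Of the 20 regions with the highest −log10 p in the main set, 4 (20%) aligned to the mitochondrial genome, and they included the 3 highest. The highest was at chr12, 97061368 to 97061856, between genes (−log10 p 7067, 99.7% identity over 365 bp). The next were at chr2, 22588592 to 22590228 (4919) and 22587518 to 22588359 (2173). Of the 20 regions with the highest signal value, 6 (30%) aligned. Over the whole main set 13 of 42316 regions aligned, with a median signal value of 24.7 against 7.23 for the others. Reads of mitochondrial DNA placed at nuclear copies are a candidate explanation for the 4 aligned regions of the highest −log10 p. They are not one for the other 16 of those 20, which did not align. No biological explanation was tested.

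Of the 20 gene lists whose promoters differed from those of other genes, 60% lost the call against random lists matched on promoter CpG ratio, and 0 lost it in the same permutation test without matching. The median gap between a list and its random lists fell from 37.8 to 16.9 percentage points with matching. CpG content is thus a candidate explanation for part of the pattern, and how large a part stays open, since 4 of the 12 lost lists were wholly open and could not pass, and without those 4 lists 8 of 16 calls (50%) were lost. The CpG ratio was taken within 500 bp of each gene's 5′ end, while a promoter could be open at any annotated start. CpG content at other starts, and their number, were thus not matched, so the matching cannot exclude them. In the main set 8 lists kept the call, which the CpG ratio at the 5′ end alone does not account for. They include fibroblast and Notch genes above and posterior HOX genes below. The posterior HOX list had 12.5% open against 88.7% in lists of the same CpG ratio. Matching was done in the main set only. By Fisher's exact test without matching, the posterior HOX, central neuron, pancreas and kidney calls ended in the overlap-based list. The fibroblast call ended without replicate 1, and the fibroblast and Notch calls ended above the median signal value. With the gene's 5′ end alone the fibroblast and central neuron calls ended (adjusted p = 0.152 and 0.0714 by that exact test). The intestine and olfactory receptor calls held in each setting tested. No biological explanation was tested, since the design has 1 group.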

How the results depend on the processing

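The correlation of signal values, 2 ways of matching random lists and random lists without matching for promoters were tested only after the data were seen. Before the IDR threshold the lists held 89320 (replicate 1) and 67135 regions (replicate 2). The share of replicate 1 regions found in replicate 2 was 59.9% with 50% of both regions, 66.4% before the threshold, 63.8% above the median signal value and 84.7% with equal numbers of regions. In the other direction it was 90.9%, 90.2%, 96.8% and 85.6%. The correlation was 0.839 as Spearman's rho, 0.945 for regions past the threshold, 0.824 for distal regions, 0.948 for promoters and 0.922 for signal values. The promoter share was 25.8% in the overlap-based list and 54.5% above the median signal value, and 42.7% to 53.7% with a replicate left out. The number of lists called by promoters was 10 in the permutation test matched on CpG ratio, against 20 by Fisher's exact test and 20 by that permutation test without matching, and by distal regions 5 above the median signal value, against 11. These parts had fewer regions or a different background by construction. With distal regions alone 0 lists fell outside in the shift. Over all lists and settings, 290 of 340 promoter results and 313 of 340 distal results were unchanged. A list called in neither setting counted as unchanged whatever its direction, and other lists had to keep both call and direction. The reversals that follow are of lists called in at least 1 of the 2 settings compared. The direction reversed in the overlap-based list for central neurons (adjusted p = 0.887) and HOX groups 1 to 5 (0.0169), and above the median signal value for fibroblast (0.644) and Notch promoters (0.848), by Fisher's exact test. Among motifs called enriched or depleted in either setting, or past the p threshold in both, the ratio turned to the other side of 1 against flanking windows for distal MEF2 (0.623), CATATG (0.799), E2F (1.64), NKX2-1 (1.45), POU (0.633), TAATTA (0.385) and nuclear receptor sites (0.364) and for promoter FOX (0.672), MEF2 (0.32), E2F (2.32), GATA (0.43), RUNX (0.427), TAATTA (0.18) and HOX-PBX sites (0.468), and above the median signal value for promoter HNF4 (1.14). The cause was not tested. Of 256 distal and 253 promoter motif results, 213 and 213 kept the call of enriched, depleted or neither. These counts include motifs called neither in both settings whose ratio crossed 1, unless the adjusted p passed in both. The numbers of enriched motifs stayed within 1.5 times in every setting. Depth is unknown, so a region absent from a list is not shown to be closed.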

Other observations

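The counts by HOX cluster and by chromosome below were chosen only after the data were seen, and the motif tests were set out before.

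Open HOX promoters differed by cluster. In paralogue groups 1 to 5, 5 of 5 genes of the A cluster and 4 of 5 of the B cluster had an open promoter, among them Hoxa5 at 8.90, Hoxa1 at 7.86 and Hoxb4 at 6.82. Hoxa5 is needed for normal lung development. In the C cluster 0 of 2 and in the D cluster 0 of 3 had one. All 5 of those genes had a promoter region in the list of replicate 1 before the IDR threshold, and 2 had one in that of replicate 2. In groups 9 to 13 the open promoters were 1 of 5 in the C cluster and 1 of 5 in the D cluster, and 0 of 4 and 0 of 2 in the A and B clusters. Before the IDR threshold 10 of these 16 genes had a region in replicate 1 and 8 in replicate 2. The difference between clusters was not tested, and neighbouring genes can share a region.

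Chromosomes differed in their density of open regions. In the main set chromosome 11 had 24.2 regions per Mb, the highest, and chromosome 14 had 12.8, the lowest of the autosomes. The X chromosome had 5.30 per Mb (907 regions), and the median autosome had 3.22 times as many. That ratio was 3.16 in replicate 1 and 2.73 in replicate 2. Per coding gene the order of the autosomes changed, with 1.81 regions on chromosome 11, 1.33 on chromosome 7, the lowest, and 2.80 on chromosome 18, the highest. The X chromosome had 0.957 per coding gene, and the median autosome 2.21 times as many. The Y chromosome had 8 regions. The pools held both sexes, so X and Y were present in fewer copies than autosomes, and no explanation was tested.

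The share of sites in distal regions was set against that of all other distal regions for 6 pairs of a lineage and a factor family, with Fisher's exact test, two-sided, and Benjamini-Hochberg adjustment over the 5 pairs with regions. The NKX2-1 family consensus lay in 11.8% of distal regions at alveolar and distal tip loci (12 of 102, interval 6.86 to 19.4) against 5.80% elsewhere. With p = 0.0176 and adjusted p = 0.0882 by the exact test, it did not pass the correction, so a link of these loci to NKX2-1 remains a hypothesis. ETS sites lay in 3.51% of the 57 endothelial regions against 4.67% (adjusted p = 1 by the exact test). FOX sites lay in 9.09% of the 44 fibroblast regions against 7.08% (adjusted p = 1 by the exact test). RFX sites lay in 0 of 31 airway regions and SRF sites in 0 of 26 smooth muscle regions, which allows shares of up to 11% and 12.9% (Wilson). Erythroid loci had 0 distal regions, so the GATA test had no data. With so few regions per lineage, these pairs cannot be told apart from chance in either direction.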
